A study of Mus musculus with 12 samples.

How the data were processed

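Gene expression was measured in the cortex of mouse embryos at embryonic day 14, in a rostral and a caudal piece, from AP2gamma (Tfap2c) knockout animals (KO) and wild-type animals (WT). Each of the 4 groups held 3 arrays, 12 in all, and every array carried a different animal number. Caudal KO arrays came from animals 1, 2 and 13, caudal WT arrays from animals 4, 6 and 14, rostral KO arrays from animals 7, 8 and 15, and rostral WT arrays from animals 10, 12 and 16. Per the labels, 400 ng of total RNA were amplified and labelled with biotin for hybridisation to 1-colour oligonucleotide arrays.

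The table deposited by the authors holds 1 log2 value for each of 45101 probe sets on each array. The unit was read from the values, which ran from -3.81 to 14.02 with nearly equal quartiles on all arrays, so the authors had normalised them between arrays. The labels do not name the methods for background correction, normalisation or summarisation. The values were used as deposited. The number of arrays, 3 per group, limits the precision of every comparison.

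Probe sets were assigned to genes with the platform annotation. Of these, 34958 probe sets named 1 gene, and 932 that named several genes were not used. Another 9211 probe sets had no gene name in the table used here and were not analysed by gene. A probe set was tested when its value exceeded 5.21, the median of the whole table, on at least 3 of the 12 arrays. Each gene was represented by its tested probe set with the highest mean, which left 24676 probe sets and 11785 of 18194 named genes. Gene positions from the mouse reference annotation (GRCm38.p6) served only to find the neighbours of Tfap2c.

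Comparisons were made with limma 3.58.1 in R 4.3.3. All 12 arrays entered 1 fit with 1 mean per group, followed by empirical Bayes moderation with an intensity trend (8 residual and 5.37 prior degrees of freedom). The 6 comparisons were KO against WT in caudal cortex, in rostral cortex and averaged over both regions, the difference of the KO effects (caudal minus rostral), and caudal against rostral cortex in WT and in KO. Effects are log2 differences with their standard errors (SE), and p-values are two-sided and adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Where all 3 arrays of a group lay at or below 5.21, the gene is called dim in that group. Its fold change is then given as a lower limit, computed after raising all lower values to 5.21, beside the measured means.

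The 28 gene lists with 519 members, of which 402 were tested, covered the following: the AP2 family, basal progenitor, radial glia, Notch pathway, upper layer neuron, deep layer and subplate neuron, young neuron, S phase, G2 and M phase, p53 and apoptosis, rostral patterning, caudal patterning, cortical hem and hippocampal, dorsal telencephalon identity, ganglionic eminence and interneuron, Cajal-Retzius cell, choroid plexus, thalamus and diencephalon, meninges and mesenchyme, vascular cell, microglia and macrophage, red blood cell, olfactory and retinal, oligodendrocyte lineage, immediate early and stress, hypoxia and glycolysis, cholesterol synthesis, and sex-linked genes. Lists share some members, such as Pax6, Eomes, Emx2 and Fgfr3. The 25 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, which compares the list with all other genes, and adjusted over the lists within a comparison. Camera with an estimated correlation between genes and fry, which asks whether a list moves on balance in either direction, were run as alternatives. Values by fry refer to this question unless its mixed test is named, which asks whether members change either way.

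The groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Genes named in the report follow a rule fixed at the same time. In each comparison except caudal against rostral in KO, the 10 genes with the largest fold change each way were named, among those past the threshold with no overlap between groups. For the difference of the KO effects, 5 each way were to be named without the condition on overlap. With fewer than 5 genes past the threshold, the 10 of smallest p were named instead. Up to 4 members of each list past the threshold, or the 3 of smallest p, could be named, and a set of AP2 and cortical marker genes was named wherever tested.

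Alternatives were quantile normalisation, median centring, values floored at 5.21, no filter, a stricter filter at the 75th percentile (7.55), another way to combine probe sets, no intensity trend, robust moderation, array weights, only the 2 groups compared, animals 13 to 16 as an additive block, a sex-linked covariate, other thresholds, and each array left out in turn. Left for after the data were seen were the fits of animals 1 to 12 only, without animals 6 and 12, with number pairs as a random block, and with the block and the sex-linked covariate together. A log2 offset of 64 was not run, since the values were already on the log2 scale.

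The fit was tested on simulated data, in which known changes were added to 200 genes. At a log2 change of 1, it recovered 80.6% of the genes in caudal cortex, 74.6% in rostral cortex, 82.1% averaged over both regions and 50.7% for the difference of the KO effects. At a change of 0.5, the shares were 28.4%, 22.4%, 52.2% and 11.9%. Each of these sizes was given to 67 genes. With 200 genes changed at once, the adjusted threshold is easier to reach. The arrays gave 0 to 4 genes in these comparisons. In caudal cortex, Neurod4 (-2.31 ± 0.32, limma adjusted p = 0.077) and Tfap2c (-1.22 ± 0.19, 0.084) did not pass. The shares therefore do not show that changes of these sizes were absent where no gene passed.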

Results

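Transcript levels in embryonic mouse cortex were measured on 12 arrays in 4 groups of 3, formed by region (rostral or caudal) and AP2gamma genotype (KO or WT). AP2gamma is a transcription factor encoded by Tfap2c, and the title of the series concerns its part in setting the number of basal progenitors, the dividing cells that settle away from the ventricular surface and produce neurons. The arrays were alike in signal. Their medians were 5.21 or 5.22 on the log2 scale, their upper quartiles ran from 7.54 to 7.56, and mean Spearman correlations with the arrays of the same group ran from 0.977 to 0.985. Arrays differed in sex-linked transcripts. Xist, which is expressed from the inactive X chromosome, was high only in caudal WT animal 6 (11.32) and rostral WT animal 12 (11.89). On the other 10 arrays, the 6 KO arrays included, Xist lay at or below 5.48 and the Y-linked gene Eif2s3y at or above 8.49. The arrays of animals 13 to 16, 1 in each group, deviated from their groups in a shared way, so values with these animals as a block are given where they alter a count.

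Tfap2c, the targeted gene, was lower in KO than in WT cortex of both regions, and more signal remained rostrally. On its probe set of highest mean, the log2 values were 7.71, 7.86 and 7.44 in caudal KO animals 1, 2 and 13, and 9.19, 8.84 and 8.64 in caudal WT animals 4, 6 and 14. In rostral cortex they were 8.11, 8.63 and 8.09 in KO animals 7, 8 and 15, and 9.06, 9.0 and 8.54 in WT animals 10, 12 and 16. All 3 probe sets of the gene gave the same picture, with 42.9%, 44.6% and 48.0% of the WT signal left in caudal KO cortex, and 66.4%, 61.0% and 61.5% left in rostral KO cortex. In caudal cortex every KO array lay below every WT array on all 3 probe sets. In rostral cortex 1 pair of arrays overlapped on 1 probe set, since KO animal 8 lay above WT animal 16. The probe sets may lie outside the deleted part of the gene, and their place relative to it was not examined here, so the source of the remaining signal stays open. Averaged over both regions, Tfap2c fell by 0.91 ± 0.14 (SE) on the log2 scale (limma adjusted p = 0.038, range 0.0017 to 0.27 over 27 alternatives, of which 12 passed). The larger loss in caudal cortex (-1.22 ± 0.19) than in rostral cortex (-0.59 ± 0.19) was a difference of -0.63 ± 0.27, which did not pass (adjusted p = 1). Among the other AP2 genes, Tfap2d differed by 0.01 in caudal and -0.51 in rostral cortex without passing, and Tfap2a, Tfap2b and Tfap2e were too dim to be tested. Tfap2e, singled out after its values were seen, read 4.91, 5.79 and 5.18 in rostral KO against 3.65, 2.47 and 3.07 in rostral WT, most of them below the median of the table, and did not pass without the filter (adjusted p = 0.90).

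Averaging over regions asks which genes depended on AP2gamma in the cortex as a whole. Only 4 of 11785 genes passed, all lower in KO cortex: Tfap2c itself, Neurod4, Eomes and Nrn1. Neurod4 encodes a basic helix-loop-helix factor of neuronal differentiation, and Eomes encodes the T-box factor that marks basal progenitors. Nrn1 encodes neuritin, a cell-surface protein that promotes neurite growth. No gene of the radial glia list or of the neuron lists passed. Caudal and rostral arrays might be pieces of the same embryos. With arrays paired by animal number as a random block, 1 gene passed, Neurod4.

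Neurod4 had the largest change of the 4 genes. It was dim in caudal KO cortex (mean 4.10 ± 0.19 SD, n = 3) against 6.42 ± 0.19 in caudal WT, and stood at 4.93 ± 0.72 in rostral KO against 7.14 ± 0.28 in rostral WT. This makes it at least 2.77-fold lower averaged over both regions (adjusted p = 0.0019, range 0.00011 to 0.082 over 26 alternatives, of which 25 passed). Eomes fell by 0.56 ± 0.08 (adjusted p = 0.038, range 0.0067 to 0.25, passed in 8 of 27 alternatives), with -0.58 in caudal and -0.55 in rostral cortex. Nrn1 fell by 0.36 ± 0.05 (adjusted p = 0.021, range 0.0067 to 0.15, passed in 13 of 27 alternatives). For Neurod4, Eomes and Nrn1, each of the 3 KO arrays lay below each of the 3 WT arrays in both regions, as the plot of the 4 genes shows. No overlap in either region, with the same direction in both, was found for 139 genes, 1.18% of those tested. Chance gives 0.5% if caudal and rostral arrays are independent. If they are pieces of the same embryos, chance gives a larger share, so an excess over chance is not established.

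**Figure D1:**
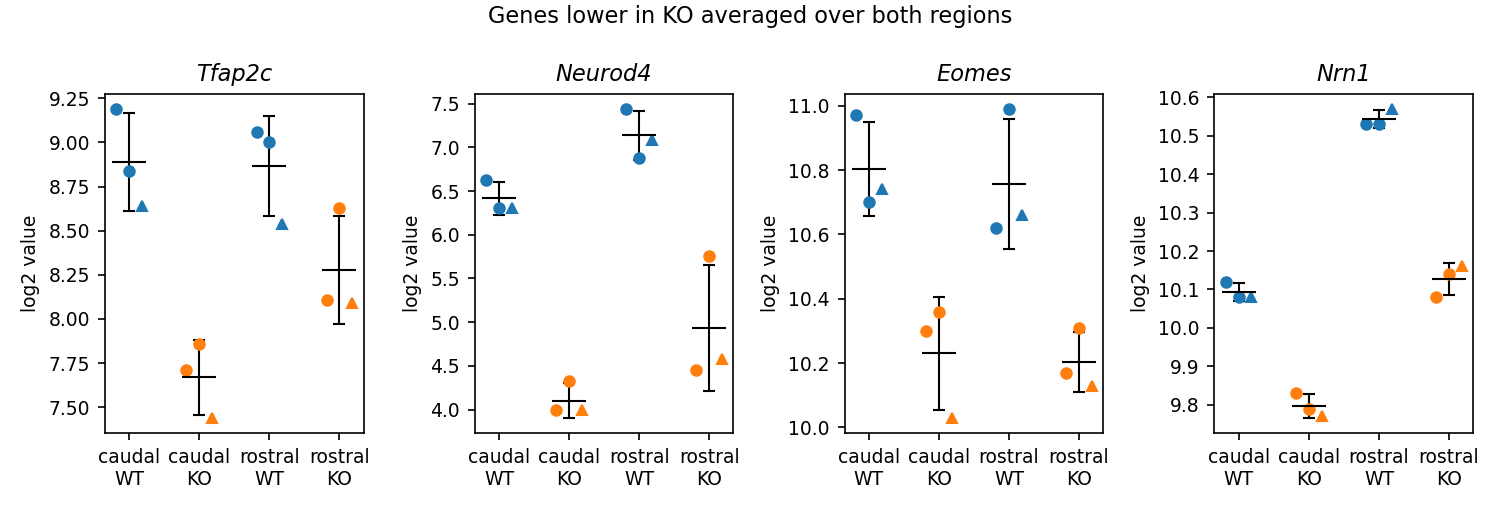
Log2 value of each array (points, n = 3 per group, triangles for animals 13 to 16) and group mean ± SD for the 4 genes that passed in KO against WT averaged over both regions. KO points lie below WT points in each region for Neurod4, Eomes and Nrn1, while Tfap2c overlaps in rostral cortex.

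The other genes of smallest p did not pass. Mt2, a metallothionein that binds zinc and copper, differed by -1.20 ± 0.20 (adjusted p = 0.073). The RNA-binding proteins Hnrnph2 (0.46) and Rbm45 (0.47) had the same adjusted p. The ubiquitin ligase adaptor Wsb1 (0.39) and the receptor-like Rell1 (-0.49) followed at 0.087 each, and 1 further gene of this set is not reported here. At an unadjusted p under 0.05 there were 887 of 11785 genes, a larger share than the 0.05 that chance gives, but genes are not independent. With animals 13 to 16 as a block, 20 genes passed (10 higher, 10 lower), the 4 genes above among them. Without any of 7 arrays (caudal KO 2 or 13, caudal WT 4 or 6, rostral KO 7, rostral WT 10 or 12) 1 gene passed, Neurod4 each time, and without rostral KO 8 or rostral WT 16 there were 2, Neurod4 and Tfap2c.

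Most other basal progenitor genes stayed near their WT level. Of the 26 genes on that list, 18 were lower and 8 higher in KO cortex, with a median of -0.05, and 2 passed over all genes tested. Adjusted over the list alone, Neurod4, Eomes and the kinesin gene Kif26b (-0.40) were lower, and the Notch ligand gene Dll3 (0.34) and the cell cycle inhibitor gene Cdkn1c (0.31) were higher. Neurog2, the proneural factor upstream of Eomes, differed by -0.09. By camera the list did not pass (adjusted p = 0.10, and 0.97 with an estimated correlation). By fry's mixed test the list passed (adjusted p = 2e-09, with 0.0084 in caudal and 4.2e-05 in rostral cortex). Members that change in opposite directions, or a few strong members, can give this result. Radial glia genes, which mark the apical progenitors that give rise to basal ones, had a median of 0.00 with 16 of 30 higher, and Pax6 differed by -0.03. The radial glia gene of smallest p was the glutamate transporter gene Slc1a3 (0.57, adjusted p = 0.19), the only one higher adjusted over the list alone. It did not overlap between KO and WT in either region and passed with animals 13 to 16 as a block (0.033). Genes of the S phase (median -0.04, 15 of 23 lower) and of the G2 and M phases (median -0.05, 22 of 29 lower) did not pass as lists (adjusted p = 0.68 and 0.53). In animals 1 to 12 the G2 and M phase list had a median of -0.13 and in animals 13 to 16 of 0.09, so its direction differed between these sets of animals. In animals 1 to 12 alone 6 lists passed at the preset correlation, all of which had an adjusted p of 0.97 over all arrays with an estimated correlation. These were the G2 and M phase (adjusted p = 0.00017), S phase (0.019), basal progenitor (0.022) and hem (0.017) lists as lower, and the deep layer (0.002) and young neuron (0.049) lists as higher.

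Over all arrays, neuronal identity genes showed small differences that did not pass. The layer marker Tbr1 differed by 0.24 and Cux2 by 0.34, the latter with 0.68 in caudal and 0.00 in rostral cortex and with probe sets that went both ways. The upper layer gene Lmo4 was lower (-0.38, adjusted p = 0.21). Upper layer genes had a median of 0.11 with 11 of 16 higher, and deep layer and subplate genes had a median of 0.08 with 12 of 19 higher. Emx1, which specifies dorsal cortex, differed by -0.36 (adjusted p = 0.61), and the areal patterning gene Nr2f1 by -0.15. No list passed by camera in this comparison (smallest adjusted p = 0.069 for vascular genes, and 0.97 with an estimated correlation), and none passed by fry. At an unadjusted p under 0.05, 6 lists were called by camera. With animals 13 to 16 as a block 2 lists passed, vascular genes higher and cortical hem genes lower, and neither with an estimated correlation as well (adjusted p = 0.99 for each).

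In caudal cortex the comparison asks what AP2gamma loss does in the region from which occipital areas arise. No gene passed there with limma. An unadjusted p under 0.05 was found for 478 of 11785 genes, a smaller share than the 0.05 that chance gives. With the block 4 genes passed, all lower: Tfap2c, Neurod4, Mt2 and Lgals7. The genes of smallest p again included the target and the basal progenitor factors. By camera at the preset correlation 5 lists passed, with genes of the medial edge of the cortex lower and genes of deep layer neurons higher among them. None of the 5 passed with an estimated correlation (adjusted p = 0.71 for each).

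Neurod4 (-2.31 ± 0.32, at least 2.30-fold lower, adjusted p = 0.077), Mt2 (-1.83 ± 0.28, 0.084) and Tfap2c (-1.22 ± 0.19, 0.084) headed the genes that did not pass. They were followed by the galectin gene Lgals7, dim in KO (at least 1.48-fold lower), the zinc transporter gene Tmem163 (-0.92), the ribosomal gene Mrpl57 (-0.45), Lmo4 (-0.59) and Eomes (-0.58). The neuronal gene Scrn1 (0.81) and the neural crest regulator gene Kctd15 (-0.45) completed the 10. Leaving out 1 array gave 1 gene in 4 cases: Mt2 without caudal KO 1, Kptn without caudal WT 4, Mdga2 without caudal WT 14 and Neurod4 without rostral KO 8. These names were chosen after the values were seen. KO and WT arrays did not overlap for 886 genes (7.52%), where chance gives 10%.

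The 22 cortical hem and hippocampal genes mark the signalling centre at the medial edge of the cortex and the hippocampal field beside it. Of the 16 tested, 15 were lower in caudal KO cortex, with a median of -0.49, or -0.30 with dim values raised to 5.21 (adjusted p = 0.00066, 0.71 with an estimated correlation, range 1.2e-08 to 0.77 over 22 alternatives). Examples are Wnt8b (-1.49 ± 0.62), the BMP target Id3 (-0.74 ± 0.31) and Wnt3a (-2.64, but -0.08 with dim values raised), none of which passed. The fall was not shared by all KO arrays. Over the tested hem genes, caudal KO 1 had a mean of 7.21, against 7.24, 7.33 and 6.6 in WT 4, 6 and 14. Caudal KO 2 and 13 had means of 6.15 and 5.85. Choroid plexus genes, of the tissue that adjoins the hem, were lower for all 5 tested members (median -0.57, adjusted p = 0.034, 0.71 with an estimated correlation), among them Folr1 (-1.41) and Clic6 (-0.57). Their median was -0.14 (adjusted p = 0.54) without caudal WT 6, the WT array with by far the highest mean over these genes (6.75, against 4.73 and 3.82 in WT 4 and 14 and 3.41 to 4.63 in KO). Basal progenitor genes were lower (adjusted p = 0.034, 0.71 with an estimated correlation), but with a median of -0.05 and a mean of -0.15, and their genes of smallest p were Neurod4 and Eomes. Hypoxia and glycolysis genes behaved alike (median -0.05, mean -0.18, adjusted p = 0.034, 0.71 with an estimated correlation), led by Mt2, Mt1 and Ldha. Deep layer and subplate genes were higher for 16 of 19 members (median 0.10, adjusted p = 0.024, 0.71 with an estimated correlation), with a median of 0.17 in animals 1 to 12 and -0.02 in animals 13 to 16. Among them were Ldb2 (0.63) and Pcp4 (0.44), against Crym at -1.62. Adjusted over the list alone, 2 basal progenitor and 2 hypoxia genes were lower, and none of the other 3 lists had a gene past the threshold. All 5 lists also passed with the block. Over 22 alternatives their adjusted p reached 0.77, by fry, and the last 4 passed in 13 to 17 of them. Without caudal KO 13 the hem list (median -0.29, adjusted p = 0.12) and the hypoxia list (0.01, 0.33) did not pass and had smaller medians, and the choroid plexus (-0.51, 0.22) and deep layer (0.13, 0.33) lists did not pass with medians of about the same size. Without caudal WT 4, the basal progenitor (-0.01, 0.37), hypoxia (0.01, 0.14) and deep layer (0.07, 0.28) lists did not, nor did basal progenitor genes without caudal KO 1 (0.10) or 2 (0.20). Choroid plexus and hypoxia genes did not pass without caudal KO 2 (0.081 each), nor hypoxia genes without caudal WT 6 (0.10).

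**Figure D2:**
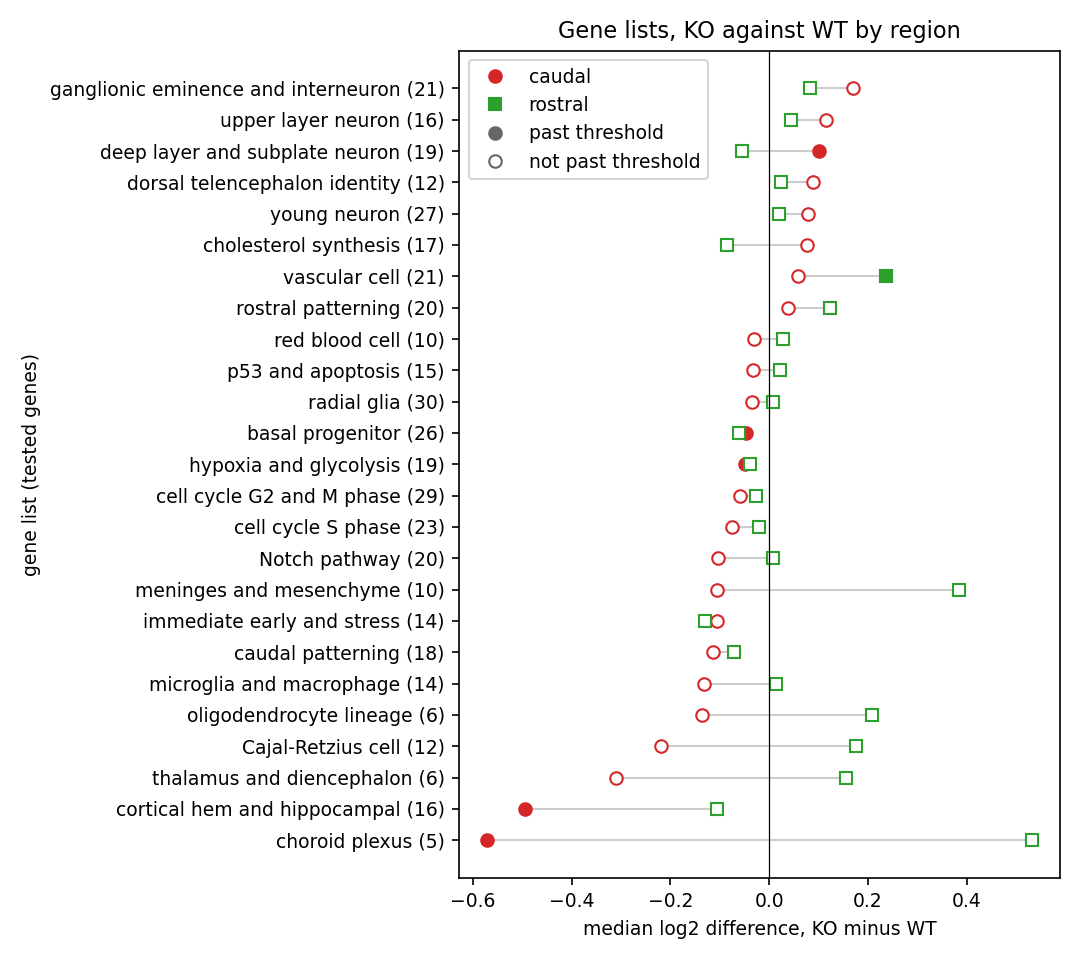
Median log2 difference between KO and WT of the members of each gene list in caudal (circles) and rostral (squares) cortex, filled where the list passed by camera, with the number of tested genes in brackets. The hem and choroid plexus lists lie at -0.49 and -0.57 in caudal cortex, and the vascular list lies at 0.24 in rostral cortex.

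In rostral cortex the same question is asked for the region from which frontal areas arise. No gene passed with limma, and none passed with the block. An unadjusted p under 0.05 was found for 789 of 11785 genes. This is a larger share than the 0.05 that chance gives, but genes are not independent. Neurod4 and Eomes were again among the genes of smallest p, and Tfap2c was not. The only list past the threshold at the preset correlation was that of vascular cells, with higher values in KO cortex, and it did not pass with an estimated correlation (adjusted p = 0.97).

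Neurod4 differed by -2.21 ± 0.32 (at least 3.35-fold lower, adjusted p = 0.12), and Nrn1 by -0.42 ± 0.07 (0.15). The other genes of smallest p were Wsb1 (0.57), the endosomal sorting gene Snx2 (0.61), Alkbh7 (-0.83), Rbm45 (0.57), Hnrnph2 (0.53), Lmo7 (-1.40), the splicing gene Snrnp27 (-0.38) and Eomes (-0.55). Tfap2c stood at -0.59 ± 0.19 (adjusted p = 0.63). Without rostral KO 8, 1 gene passed, Neurod4. KO and WT arrays did not overlap for 1528 genes (12.97%), against 10% by chance. Of 21 vascular genes 15 were higher (median 0.24, adjusted p = 0.036, 0.97 with an estimated correlation, range 0.00053 to 0.98), among them Pdgfrb (0.52), Cldn5 (0.31) and Egfl7 (0.29), and none passed. The adjusted p was 0.051 with the block, and the median was 0.08 in animals 1 to 12 and 0.52 in animals 13 to 16. Without rostral KO 15 it was 0.05 (adjusted p = 0.89), and the list did not pass without rostral WT 10 (0.078) or 12 (0.065) either. Meningeal genes followed the same course without passing (median 0.39, 8 of 10 higher), with -0.09 and 1.17 in these sets of animals.

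The difference of the KO effects asks whether AP2gamma loss acts differently in caudal and in rostral cortex. No gene passed with limma. An unadjusted p under 0.05 was found for 358 of 11785 genes, a smaller share than the 0.05 that chance gives. With the block 1 gene passed, Snx2. For the basal progenitor factors no difference was detectable (-0.10 ± 0.46 for Neurod4 and -0.03 ± 0.17 for Eomes). Neurod4 is dim in caudal KO cortex, and with dim values raised its KO effects were -1.20 caudally and -1.74 rostrally. Across genes, which are not independent replicates, the KO effects of the regions correlated with r = 0.154. Of 108 genes with an unadjusted p under 0.01 in caudal cortex, 76 had the same sign in rostral cortex.

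Snx2 had the smallest p (-0.98 ± 0.16, adjusted p = 0.34), with a KO effect of 0.61 in rostral cortex. Mrpl57 (-0.66), Tmem163 (-1.17), Ccdc14 (1.72), Mrpl11 (0.69), Tspan14 (0.68) and Akap10 (-1.18) followed, and Flnc, Aanat and Aqp2 were dim in some groups and are given without a fold. By camera 5 lists passed, each with a lower KO effect in caudal cortex: choroid plexus, Cajal-Retzius cell, cortical hem and hippocampal, radial glia and Notch pathway genes. None passed with an estimated correlation, where all 5 had an adjusted p of 0.66, and none passed by fry. No member of these lists passed over all genes tested. In animals 1 to 12 only 2 lists passed. Without caudal KO 13 or without rostral KO 15, 0 passed, while 3 passed without rostral WT 16 and 9 without caudal WT 14.

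Caudal against rostral cortex in WT asks which genes differ between the dissected pieces of normal cortex. Of 11785 genes 111 passed, 30 higher and 81 lower in caudal cortex. Known areal patterning genes were among the strongest. Genes of caudal and lateral cortex such as Nr2f1 and Nr2f2 were higher caudally, and targets of the rostral FGF signal such as Sp8, Etv5 and Il17rd were lower. Genes of the ganglionic eminences, the ventral source of interneurons, were lower in the caudal pieces at the preset correlation (adjusted p = 0.63 with an estimated correlation). Their mean was 7.08 to 7.48 on rostral and 5.88 to 6.7 on caudal WT arrays. Position within the cortex and other tissue in the pieces cannot be told apart for the 111 genes.

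Nr2f2 (2.77 ± 0.31, adjusted p = 0.0016) and Nr2f1 (1.93 ± 0.26, 0.0045) encode orphan nuclear receptors that specify caudal areas. Fgfr3, an FGF receptor graded along the same axis, was higher by 1.87 ± 0.24 (0.004). The other genes with the largest rise in caudal cortex were the predicted gene Gm38604, dim rostrally (at least 3.41-fold higher), the GABA receptor gene Gabra2 (2.21), the caveolin genes Cav1 (1.82) and Cav2 (1.48), the secreted factor gene Tafa2 (1.56), the splicing factor gene Rbm20 (1.53) and the neuronal calcium sensor gene Hpca (1.40). Cav1 passed in only 10 of 28 alternatives (limma adjusted p up to 0.27) and Cav2 in 14 of 27 (up to 0.23). Among genes lower in caudal cortex, the FGF antagonist gene Il17rd fell by 1.90 ± 0.27 (0.0061), the FGF target Etv5 by 1.28 ± 0.21 (0.012) and Sp8, which specifies frontal cortex, by 1.53 ± 0.32 (0.037). The ligand gene Fgf18 was dim caudally (at least 2.26-fold lower, means 4.24 and 6.39). The striatal and septal genes Isl1 (at least 3.97-fold lower, means 3.19 and 7.2), Zic1 (-2.62 ± 0.37, 0.0058) and Olig2 (at least 2.10-fold lower, means 4.22 and 6.28) were lower too. Isl1 (limma adjusted p = 0.018) did not pass with dim values raised (0.12), and passed in 21 of 28 alternatives. The list of largest falls also held the melanin synthesis gene Dct (-3.66 ± 0.65), the pluripotency factor gene Sall4 (at least 1.97-fold lower), BC034090 (at least 3.36-fold lower), Thsd4 (-2.44) and As3mt (at least 2.50-fold lower).

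**Figure D3:**
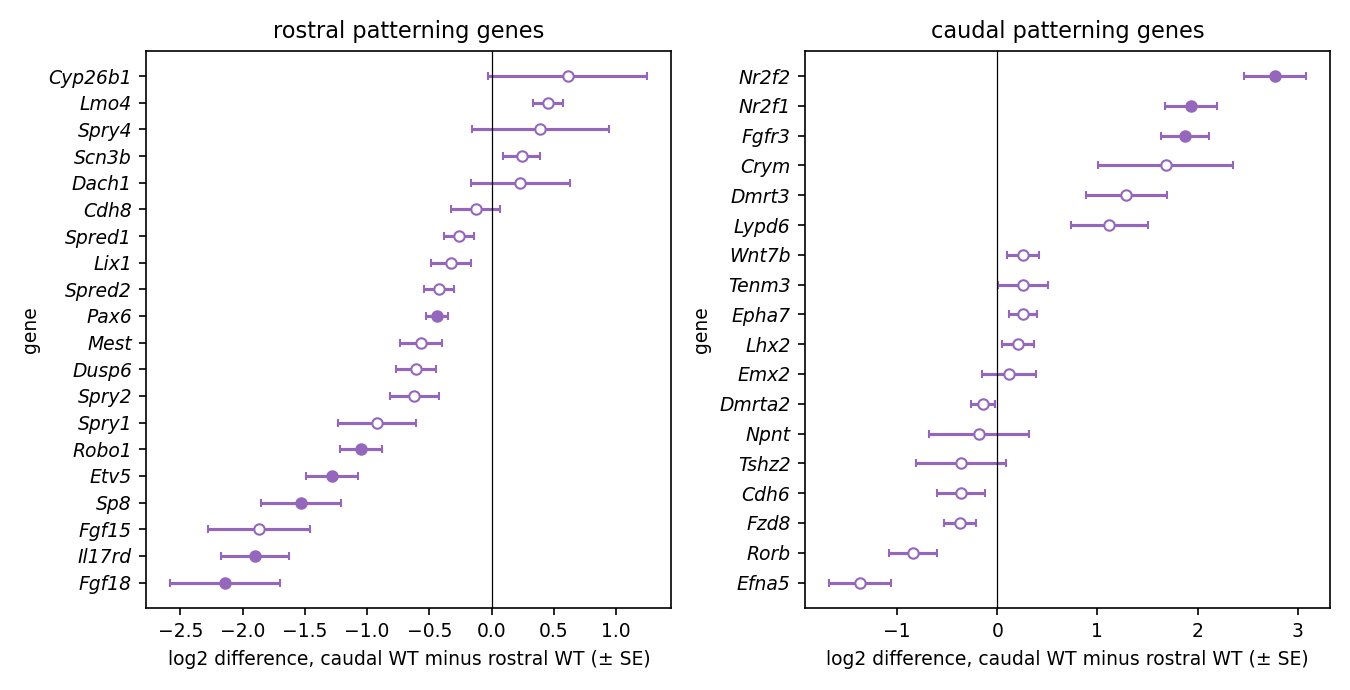
Log2 difference (± SE, n = 3 per group) between caudal and rostral WT cortex for the tested rostral and caudal patterning genes, with filled points for genes that passed. Nr2f2, Nr2f1 and Fgfr3 passed above 0, and Fgf18, Il17rd, Sp8, Etv5, Robo1 and Pax6 below 0.

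Of the 20 tested rostral patterning genes, 15 were lower in caudal cortex (median -0.50, adjusted p = 5.6e-08, and 0.019 with an estimated correlation). 6 of them passed over all genes tested, and 12 were lower and 1 higher adjusted over the list alone. Pax6, highest rostrally by its main probe set (-0.44 ± 0.09, adjusted p = 0.033), showed -0.07 over the mean of its probe sets (0.97, the top of a range from 0.0078 over 28 alternatives). Caudal patterning genes were higher for 11 of 18 members (median 0.23, adjusted p = 0.0038, 0.21 with an estimated correlation), with 3 past the threshold, and 5 higher and 2 lower adjusted over the list alone. Ganglionic eminence and interneuron genes were lower for 15 of 21 (median -0.77, or -0.44 with dim values raised, adjusted p = 0.00025, 0.63 with an estimated correlation). G2 and M phase genes were lower for 28 of 29 (median -0.17, adjusted p = 0.017, 0.87 with an estimated correlation), and none passed alone. Young neuron genes passed as higher with a median of 0.01 (adjusted p = 0.027, 0.68 with an estimated correlation). Over 22 alternatives the highest adjusted p was 0.019 for rostral patterning, 0.21 for caudal patterning, 0.63 for ganglionic eminence, 0.97 for G2 and M phase and 0.84 for young neuron genes. Without caudal WT 4 the ganglionic eminence list did not pass (0.072). The G2 and M phase and young neuron lists did not pass without caudal WT 6 (0.23 and 0.16), caudal WT 14 (0.97 and 0.76) or rostral WT 12 (0.70 and 0.48). Single genes from further lists were Foxp2 (-1.13) of deep layers, Calb2 (-1.04), Rcor2 (-0.83), the guidance receptor gene Robo1 (-1.05) and Mt1 (1.13), which all passed. Eomes (0.05), Neurog2 (-0.21), Tbr1 (-0.49) and Neurod4 (-0.72) did not pass.

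The count of 111 genes depended on single arrays. It was 27 without rostral WT 10, 44 without rostral WT 12, 48 without rostral WT 16, 63 without caudal WT 14, 71 without rostral KO 8 and 73 without caudal KO 2. With the block 257 genes passed, the 111 among them. WT arrays of the regions did not overlap for 1644 genes (13.95%), against 10% by chance.

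The same contrast in KO asks whether differences between the pieces persist in KO cortex. In KO cortex 112 genes passed, 26 higher and 86 lower caudally. Nr2f1 (2.13, adjusted p = 0.0027), Nr2f2 (1.91, 0.013) and Fgfr3 (1.60, 0.0079) rose caudally, and Sp8 (-2.14, 0.0079), Il17rd (-1.86, 0.0079) and Etv5 (-1.19, 0.019) fell. Of the 111 genes called in WT, 108 had the same direction in KO and 50 passed in both genotypes, all in the same direction, where independence would give 0.66. The genotypes share no array, but both sets of calls use the same estimate of each gene's spread. They are therefore not independent, and 0.66 is only a rough reference. Across genes the log2 differences correlated with r = 0.522. Rostral patterning genes were lower (median -0.52, adjusted p = 4.5e-07, 0.028 with an estimated correlation) and caudal patterning genes higher by the test (median 0.21, 0.014, 0.31 with an estimated correlation). Of the latter 9 were higher and 9 lower, 3 passed as higher and 1 as lower, and the median was 0.24 in animals 1 to 12 and -0.01 in animals 13 to 16. The count was 20 without rostral KO 8, 36 without rostral KO 15, 40 without caudal KO 2, 48 without caudal KO 1 and 52 without caudal KO 13, and 342 with the block. No overlap between the regions was found for 2462 genes (20.89%), against 10% by chance.

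**Figure D4:**
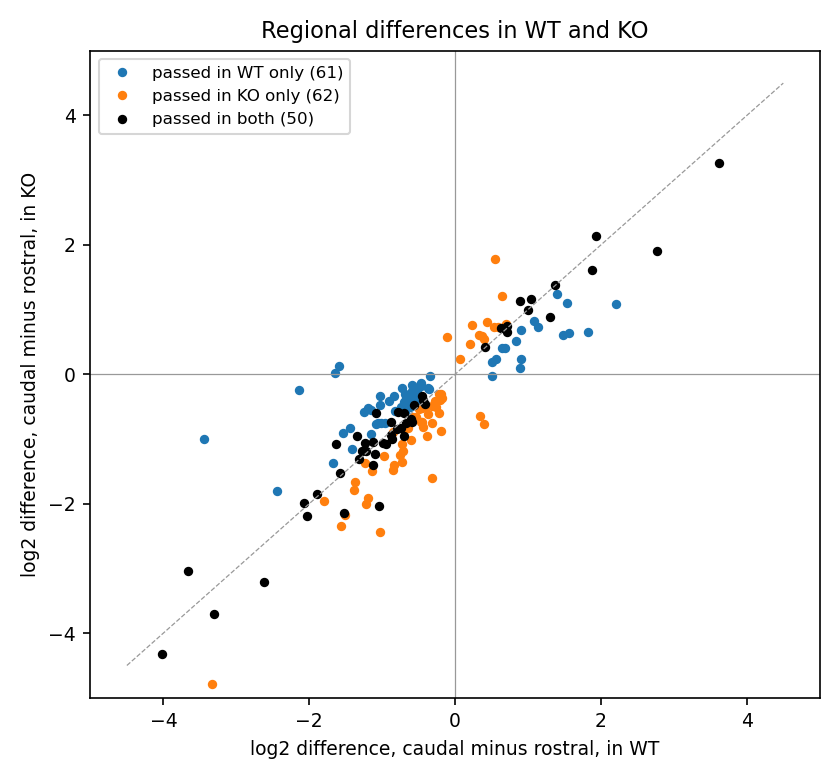
Log2 difference between caudal and rostral cortex in KO (vertical axis) against WT (horizontal axis) for the genes that passed in WT, in KO or in both (1 point per gene, dashed line at equal values). The 50 genes that passed in both lie in the quadrants of equal sign.

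Another 11 lists passed in KO cortex, each at the preset correlation only, and in 12 to 20 of 22 alternatives. The cell cycle lists were lower caudally, G2 and M phase genes by a median of -0.27 with 26 of 29 lower (adjusted p = 0.00077, 0.52 with an estimated correlation) and S phase genes by -0.14 with 19 of 23 lower (0.010, 0.52 with an estimated correlation). Basal progenitor genes (-0.17, 0.020, 0.31 with an estimated correlation) and Notch pathway genes (-0.21, 0.037, 0.52 with an estimated correlation) were lower too. So were ganglionic eminence genes (-0.67, or -0.16 with dim values raised, 0.0073, 0.49 with an estimated correlation) and oligodendrocyte lineage genes (-0.63, or -0.46 with dim values raised, 0.014, 0.31 with an estimated correlation). Choroid plexus (-0.83, or -0.28 with dim values raised, 0.037, 0.49 with an estimated correlation) and microglia genes (-0.36, or -0.16 with dim values raised, 0.022, 0.31 with an estimated correlation) were lower caudally as well. Meningeal genes (-0.62, or -0.52 with dim values raised, 0.012, 0.52 with an estimated correlation) rested on rostral KO 15, whose mean over them was 7.70 against 6.07 and 5.96 in rostral KO 7 and 8. Without this array their median was -0.17 (0.90), and it was -0.13 in animals 1 to 12 against -1.44 in animals 13 to 16. Cholesterol synthesis genes were higher (0.12, 0.0058, 0.31 with an estimated correlation), as were young neuron genes (0.08, 0.036, 0.53 with an estimated correlation). Without rostral KO 15 the Notch (0.25), ganglionic eminence (0.10), choroid plexus (0.18), microglia (0.13) and oligodendrocyte (0.13) lists did not pass. Without caudal KO 13 the Notch (0.21), young neuron (0.54), S phase (0.070), choroid plexus (0.12, median -0.30) and oligodendrocyte (0.11) lists did not. Without caudal KO 2 the basal progenitor (0.083), Notch (0.050), choroid plexus (0.062) and meningeal (0.050) lists did not, nor young neuron genes without rostral KO 7 (0.11). Whether a list differed between WT and KO is the same test as the difference of the KO effects, in which only the choroid plexus and Notch lists of these passed, and neither with an estimated correlation (0.66).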

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

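Of the tests in this part, the block for animals 13 to 16, the estimated correlation between genes, and the fit of animals 1 to 12 were chosen as tests of these results after they were seen. For 5 gene lists, a test of the difference itself at the preset correlation called the KO effect different between caudal and rostral cortex. None of the 5 passed with an estimated correlation (adjusted p = 0.66 for each). The median difference was -1.1 for choroid plexus genes, -0.52 for Cajal-Retzius cell genes, -0.35 for cortical hem and hippocampal genes, -0.11 for Notch pathway genes and -0.05 for radial glia genes. With dim values raised to 5.21, it was -0.36 for choroid plexus and -0.12 for hem and hippocampal genes. The first 3 lists describe the medial edge of the cortex and what arises there, but meningeal genes (-0.43, 9 of 10 lower, adjusted p = 0.052) and thalamus and diencephalon genes (-0.33, 5 of 6 lower, 0.18) lay in the same direction without passing. In choroid plexus genes the KO effect was -0.57 caudally and 0.53 rostrally, in Cajal-Retzius genes -0.22 and 0.18, and in hem and hippocampal genes -0.49 and -0.11. In Notch pathway genes it was -0.10 and 0.01, and in radial glia genes -0.03 and 0.01. The rostral rise of choroid plexus genes (3 of 5 higher) was 0.03 with dim values raised. It was -0.01 in animals 1 to 12 and 0.74 in animals 13 to 16, so opposite KO effects in the 2 regions are not established.

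The result depended in part on animals 13 to 16, but not in 1 direction. In animals 1 to 12, with 2 arrays per group and so less power, only 2 lists passed. Without caudal KO 13 or without rostral KO 15, 0 passed, while 3 passed without rostral WT 16 and 9 without caudal WT 14. The median differences in animals 1 to 12 against 13 to 16 were -0.18 and -0.93 for Cajal-Retzius, -0.06 and -0.35 for Notch pathway and -0.07 and -0.29 for radial glia genes, but -1.13 and -1.50 for choroid plexus and -0.30 and -0.13 for hem and hippocampal genes. Without caudal KO 13 the median was -0.07 for hem and hippocampal, -0.26 for Cajal-Retzius and -0.04 for Notch pathway genes, and without caudal WT 4 that of Notch pathway genes was 0. Rostral KO 15 had a mean of 7.70 over the meningeal genes, against 6.07 and 5.96 in rostral KO 7 and 8. Without caudal WT 6 the choroid plexus median was -0.62 (adjusted p = 0.21, range 0.002 to 0.92 over 22 alternatives). With these animals as a block 4 of the 5 lists passed, which decides nothing about an additive offset, because each group holds 1 of them and a block cannot alter the differences.

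Correlation between the genes of a list is a candidate explanation, and 0 of the 5 lists passed with a correlation estimated from the arrays. But no list passed this way for KO against WT in caudal cortex, in rostral cortex or averaged either. The test therefore does not single out this explanation for the 5 lists. A varying amount of medial tissue in the dissected pieces stays open: within groups the choroid plexus and hem lists deviated together across the 12 arrays (Pearson r = 0.61, exact permutation p = 0.11; Spearman rho = 0.64, exact p = 0.11; 1296 permutations). It was the only relation computed, and r was 0.59 without caudal WT 6 and 14. A weaker medial signalling centre in caudal KO cortex cannot be told apart from a different plane of dissection, since both would lower the same genes.

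Of 100 splits of the genotype labels within regions, the real one included, 44 gave at least 5 lists. The highest of the others gave 13, so chance cannot be excluded for the number of lists. For genes the real count was 0, which any split reaches (100 of 100). The highest other split gave 72 genes and put both caudal arrays of animals 13 to 16 under the same genotype label and both rostral ones under the opposite label. So high a count points to a structure of the samples, but this placing alone does not produce it, since 7 further splits with it gave 0 to 9 genes. With these animals as a block, 1 gene passed for the real labels.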

How the results depend on the processing

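Among the alternatives below, animals 1 to 12 only, the fit without animals 6 and 12, number pairs as a random block, and the number block with the sex-linked covariate were chosen after seeing the data. No animal number recurs between groups, so the labels pair no arrays. Arrays whose numbers differ by 6 or, for animals 13 to 16, by 2 were paired only in the fit with number pairs as a random block. A log2 offset of 64 was not run, since the values are log2, and Neurod4 has no value under the stricter filter, which removed it. The 30 named results for genes past the threshold kept their direction in all 827 values, and 637 of these also stayed past the threshold. Of 3300 values for the lists, 2768 kept direction and side of the threshold, 160 lost the threshold and 122 gained it. In another 248 the direction changed with neither value past the threshold. In 2 it reversed with at least 1 of the values past the threshold. Quantile normalisation, median centring, robust moderation and the stricter filter left each count of genes within 1.5 times its value. Except where fewer arrays or another threshold shows it, the cause was not tested.

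With animals 13 to 16 as a block, 4 genes passed in caudal cortex, 20 averaged, 1 for the difference, 257 for caudal against rostral in WT and 342 in KO, and 0 lists passed in rostral cortex and 2 averaged. With the block and the sex-linked covariate, 2 genes passed in caudal cortex, 1 in rostral cortex, 1 for the difference, 261 in WT and 352 in KO, with 8 lists in caudal cortex, 2 in rostral cortex and 6 averaged. With the sex-linked covariate alone, 2 genes passed averaged, and 3 lists in caudal cortex, 2 in rostral cortex and 1 averaged. In animals 1 to 12 only, with 2 arrays per group, 1 gene passed averaged (Rbm45, higher), 72 in WT and 38 in KO, with 0 lists in rostral cortex, 6 averaged, 2 for the difference and 8 in KO. Without animals 6 and 12, 1 gene passed averaged and 22 in WT, with 8 lists in caudal cortex, 0 in rostral cortex and 1 averaged. With number pairs as a random block, 1 gene passed averaged, 320 in WT and 385 in KO. With values floored at the median, 4 genes passed in rostral cortex (Cdhr1, Nrn1, BC034090 and Neurod4, named after their values were seen) and 2 averaged. With no intensity trend, 2 genes passed averaged, 69 in WT and 56 in KO, and with array weights 2 in rostral cortex, 10 averaged and 637 in KO. With only the 2 groups compared, 61 genes passed in WT and 72 in KO. With all probe sets separately, 2 passed averaged. Without a filter on dim probe sets, 2 lists passed in caudal cortex, 2 in rostral cortex, 4 averaged and 2 for the difference, and with the mean of probe sets 2 in rostral cortex and 3 averaged.

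At an adjusted p under 0.1, 3 genes passed in caudal cortex, 12 averaged, 239 in WT and 280 in KO. At an unadjusted p under 0.01 and a 1.5-fold change, the counts were 56 in caudal cortex, 52 in rostral cortex, 37 averaged, 37 for the difference, 295 in WT and 297 in KO. With an estimated correlation, and likewise by fry, 0 lists passed in caudal cortex, 0 in rostral cortex, 0 for the difference, 1 in WT and 1 in KO.

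The averaged change of Tfap2c kept its direction in all alternatives and lost the threshold in some. It was -0.91 (adjusted p = 0.063) with floored values, -0.91 (0.25) with no intensity trend, -0.87 (0.17) with the sex-linked covariate, -0.95 (0.082) in animals 1 to 12, -0.89 (0.27) without animals 6 and 12 and -0.91 (0.079) with number pairs, in a range of 0.0017 to 0.27.

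Leaving out 1 array at a time gave 0 to 1 genes in caudal cortex, 0 to 1 in rostral cortex, 1 (without caudal KO 2, for example) to 4 averaged, 27 (without rostral WT 10) to 134 (without caudal KO 13) in WT and 20 (without rostral KO 8) to 143 (without caudal WT 14) in KO. Tfap2c ranged from -0.99 (without rostral KO 8) to -0.83 (without caudal WT 4, adjusted p = 0.12). Lists ranged from 1 (without caudal KO 13) to 8 (without caudal WT 6) in caudal cortex, 0 (without rostral KO 15) to 3 (without rostral WT 16) in rostral cortex, and 0 to 8 (without caudal WT 14) averaged. They ranged from 0 (without caudal KO 13) to 9 (without caudal KO 1) for the difference, 3 (without caudal WT 6) to 6 in WT and 7 (without rostral KO 15) to 16 (without caudal KO 1) in KO.

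The list of G2 and M phase genes reversed in 2 cases, by its test. In WT, caudal against rostral, the median was -0.05 with the test pointing upward without animals 6 and 12 (adjusted p = 0.95, range 1.9e-09 to 0.97). In caudal KO against WT, the median was 0.08 without caudal WT 4 (adjusted p = 0.043) and -0.21 without caudal WT 14 (also past the threshold), the limits over single arrays. Signal over background limits what can be said of dim genes, whose fold changes are given as lower limits.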

Other observations

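In this part, the test that animals 13 to 16 were a chance choice and the test of embryo pairs were chosen after the result was seen. The 4 arrays of animals 13 to 16, 1 in each group, deviated from their group means in a shared way, with a mean correlation of 0.26. Of the 81 choices of 1 array per group, only this 1 reached that value, and the highest other gave 0.13, which argues against a chance choice. In the fit with these animals as a block, 1209 of 11785 genes differed, 559 higher and 650 lower. The genes of smallest p were Ank3 (1.12) and Apc (0.70), both higher and named after their values were seen. Those that followed, such as Dync1h1 (0.89), Lrp1 (0.95) and Hectd4 (1.18), were higher too, although more genes were lower among all that differed. Young neuron genes were higher (median 0.13, 24 of 27), and G2 and M phase (-0.27, 26 of 29 lower) and S phase genes (-0.21, 21 of 23 lower) were lower, each without passing under an estimated correlation (adjusted p = 0.84).

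This pattern could reflect slightly older embryos, but the median of young neuron genes minus that of radial glia genes was 0.24, and the radial glia list (-0.10, adjusted p = 0.37) did not pass, so a difference in stage stays open. For more blood, vessel, meningeal or immune cells in these pieces, the 4 medians had opposite signs (red blood cell -0.11, microglia -0.11, vascular 0.01 and meningeal 0.21). This speaks against an increase of all 4 together, but none of the lists passed (adjusted p = 0.37 to 0.77), so the signs lie within the spread of their genes and the explanation stays open. A difference in handling or hybridisation between the sets of animals cannot be told apart from these, as no label names a batch. Because each group holds 1 of the 4 animals, the group means are shifted alike if the shift is additive.

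For the 4 genes called in KO against WT averaged over both regions, the WT groups held the 2 arrays with high Xist, so embryo sex might have contributed. Without these arrays the median size of the 4 changes was 0.96 of its value over all arrays, which argues against sex as their source. DNA of the targeted embryonic stem cells beside Tfap2c was also tested: 0.84% of 238 tested genes within 20 Mb of Tfap2c had an unadjusted p under 0.01, against 1.95% elsewhere (Fisher's exact p = 0.33, two-sided), and none of the other 3 called genes lies there. This argues against flanking DNA as their source. The basal progenitor list did not fall evenly, as Neurod4 was at least 2.77-fold lower, Eomes fell by 0.56, the median of the 26 genes was -0.05, Neurog2 differed by -0.09, and Dll3 (0.34) and Cdkn1c (0.31) were higher. The number of basal progenitors and transcription per cell were not tested separately.

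Splits of the same arrays gave the following. For KO against WT averaged, 2 of 100 splits of genotype labels within regions, the real one included, gave at least the 4 genes found. Such a count was uncommon if arrays of both regions are independent, but chance is not excluded. The share concerns the count and not any 1 gene, and Tfap2c, the target, is among the 4. If arrays were pieces of the same embryos, only 10 splits of embryos would exist, too few for a share under 0.05, and with number pairs as a random block 1 gene passed (Neurod4, with Nrn1 and Tfap2c at an adjusted p of 0.079 and Eomes at 0.15). The other split gave 8 genes and put animals 13 to 16 under 1 genotype label in each region, but 9 further splits with that placing gave 0 to 1 genes. With these animals as a block the real count was 20. No lists passed in the real split (0, reached by 100 of 100), and the highest other gave 13. For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. In caudal cortex 0 genes were found (highest other 1, 10 of 10 as large) and 5 lists (highest other 10, 7 of 10 as large). In rostral cortex 0 genes were found (highest other 0, 10 of 10) and 1 list (highest other 7, 9 of 10). Caudal against rostral in WT gave 111 genes (highest other 0, 1 of 10) and 5 lists (highest other 12, 6 of 10), and in KO 112 genes (highest other 0, 1 of 10) and 13 lists (highest other 11, 1 of 10).

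Caudal and rostral arrays whose animal numbers differ by 6 might be pieces of 1 embryo, since the 2 arrays with high Xist are animals 6 and 12. The 4 such pairs had a mean correlation of deviations of 0.14, and the highest of the other matchings had 0.11. The single pairs had 0.1, 0.2, 0.08 and 0.17, and pairs crossed within genotype had 0.02, 0.01, 0.07 and 0.08. In the fit with number pairs as a random block, the consensus correlation within pairs was 0.258. With 4 matchings the question cannot be decided, so arrays of the 2 regions may not be independent.

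The remaining lists, given for KO against WT averaged over both regions, did not pass. The medians were -0.02 for Notch pathway, 0.04 for young neuron, -0.03 for dorsal telencephalon identity, 0.05 for rostral patterning, -0.09 for caudal patterning and 0.15 for ganglionic eminence genes. They were -0.25 for hem and hippocampal, -0.29 for choroid plexus and 0.10 for Cajal-Retzius cell genes, and -0.05 for thalamus and diencephalon genes. For cell types outside the neural lineage they were 0.17 for meningeal, 0.10 for vascular, -0.03 for microglia and -0.04 for red blood cell genes. For the rest they were 0.01 for oligodendrocyte lineage, -0.11 for immediate early and stress, 0.00 for p53 and apoptosis, -0.01 for hypoxia and glycolysis and 0.01 for cholesterol synthesis genes. Medians, means and tests differed in sign for 7 lists in this comparison, 2 in caudal cortex, 4 in rostral cortex, 3 for the difference, 5 in WT and 2 in KO. With under 5 tested members, the AP2 family (2 tested, 1 passed), the olfactory and retinal genes (3 tested, median -0.11) and the sex-linked genes (4 tested, none passed) were only counted.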
